A study of Homo sapiens with 38 samples.

How the data were processed

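Expression was measured in 38 biopsies of Barrett's oesophagus from 19 patients, each sampled before and after 12 weeks on netazepide (10 patients) or placebo (9 patients). Per the labels' protocols, RNA was purified with the miRNeasy micro kit, poly(A) RNA was selected, and libraries were made with the TruSeq Stranded mRNA kit. The values were raw read counts per gene symbol that the authors deposited as a table of the whole series, with no normalisation. Per the submitters' processing notes, bcl2fastq 2.2.0 and featureCounts were used and the genome build was GRCh37. The aligner, the gene annotation, the strand setting of the counting and the treatment of reads with several matches were not given in the sources used here. Reads shared between paralogs, pseudogenes or overlapping genes are therefore uncertain, and detection limits cover counting error only, since the reads carry no molecular identifiers. The intervals of fold changes come from the fit and include the variation between patients.

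Every column of the table was matched to a sample by its name. The arm and the patient came from the labels, and the libraries of a patient before and after treatment were paired. For 1 patient the labels disagreed on the arm; the patient was counted in the netazepide arm, as the sample code and the stated group sizes have it, and alternatives left the patient out or counted the patient as placebo. The table held 25559 gene entries. Of these, 112 (XIST, TSIX and Y-linked genes) were left out of every analysis, and 26 entries with a date in place of a symbol (at most 0.154% of the counts of a library) were tested but not named. Total counts ranged from 7444670 to 14172500 per library. No pair of libraries was a duplicate: the lowest chi-square per degree of freedom over the 703 pairs was 12.7.

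Genes were kept by filterByExpr on the 4 groups, which left 15953, and libraries were scaled by TMM. Tests were made with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) at FDR 0.05 with Benjamini-Hochberg adjustment over all genes tested. The change within each arm and the difference between the changes came from 1 fit of all libraries, with 1 coefficient per patient as a replicate block and an after-against-before term for each arm. The arms were compared before and after treatment in separate fits of 19 libraries. Log2 fold changes are given with standard errors derived from the quasi-likelihood F statistic. The pairing rests on the sample codes, which give the same patient at both times. For 2 patients the number in the titles differed from that in the codes, and 1 library titled as before treatment had a code of the later time. These libraries were grouped by the time in the title, and an alternative left the 3 patients out. The pairing was checked on the deviations from the group means: the libraries of 1 patient had a median correlation of 0.521 over 19 pairs, above 0.1 in 15 of them, against -0.0445 for different patients of an arm.

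Before the data were examined, 17 gene lists (362 distinct genes, 337 of them tested) were fixed: gastrin signalling and gastrin-responsive genes, proliferation, intestinal goblet and enterocyte, gastric surface and neck mucous, gastric oxyntic parietal and chief, squamous epithelium, enteroendocrine, stem cell with Wnt and Notch, oesophageal adenocarcinoma drivers, inflammation, T and natural killer cells, B and plasma cells, macrophages with neutrophils and mast cells, fibroblasts and endothelium, smooth muscle, immediate early and heat shock, and xenobiotic metabolism. A list score is the mean log2 CPM (prior count 2) of the tested members. Its change was tested by an exact 2-sided sign-flip test over the patients of an arm, and its difference between arms by an exact 2-sided permutation of the arm labels over all 19 patients, adjusted over the 17 lists. Each list was also set against the other genes with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation) and tested with fry.

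The genes named were fixed by a rule before the data were examined: for each change comparison, the 12 largest log2 fold changes in each direction among genes past the threshold with a mean log2 CPM of at least 1 and, where fewer than 10 passed in a direction (none did), the genes of smallest p up to 10; for each comparison between arms, the 5 of smallest p in each direction; 2 to 4 members of smallest p of a list; and CCKBR, GAST, CHGA, HDC, MKI67, LGR5, DCLK1, CDX2, MUC2, TFF3, KRT5 and ATP4A. Immunoglobulin, T-cell receptor and HLA genes and genes with common deletions were not named, and 2 genes that the rule takes are left out of the text. Gene coordinates are not given, since the reference used for gene names was of another build.

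The alternatives were no replicate block, DESeq2 size factors, no filter on low counts, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom with patient as a random effect, robust empirical Bayes, each arm alone, both treatments of the patient with disagreeing labels, the squamous score as a covariate, and, for the lists, medians, a prior count of 0.5 and other scaling. Further alternatives, added after the data were seen, left out the 6 patients with a library of over 1% squamous counts, used 3 scores as covariates, left out the 3 patients whose labels disagree on number or time, left out each patient in turn (mean changes in log2 CPM of list scores and marker genes, and sign-flip tests of list scores), and applied the choices about patients to the camera tests. On simulated counts with 200 changed genes among 15953, the netazepide fit recovered 47.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 92.4% of those changed 4-fold, the difference between arms 14.9%, 44.8% and 80.3%, and the comparison before treatment 22.4%, 64.2% and 84.8%. The changed genes were drawn among those with a mean CPM of at least 1, and every gene was simulated independently of the others. Genes of the real libraries vary together, so these rates need not hold for them. Figures were drawn with matplotlib 3.10.9.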

Results

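Gene expression was measured by poly(A) RNA sequencing in biopsies of Barrett's oesophagus, the replacement of the squamous lining of the lower oesophagus by glandular mucosa, from 19 patients of a randomised trial. Patients took 25 mg of netazepide, an antagonist of the gastrin receptor CCKBR, or placebo daily for 12 weeks. Each patient gave 1 library before and 1 after treatment, so that the 38 libraries fell into placebo before (n = 9), placebo after (n = 9), netazepide before (n = 10) and netazepide after (n = 10). Total counts per library ranged from 7444670 to 14172500, with a mean of 10112000 ± 1518630 (SD, n = 38). The group means were 9279080 ± 864589 (placebo before), 9825690 ± 1247610 (placebo after), 10568400 ± 1906340 (netazepide before) and 10663100 ± 1566670 (netazepide after). Of 25559 gene entries, 15953 genes were tested.

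Marker genes of epithelial types varied widely between libraries. Genes of squamous epithelium, such as the keratins KRT4, KRT5 and KRT13 and the cornified envelope proteins of the SPRR family, took from 0.0138% to 20.9% of all counts in a library. The median was 0.0371%, with group medians of 0.0302% (placebo before), 0.0313% (placebo after), 0.0345% (netazepide before) and 0.316% (netazepide after). Of the 38 libraries, 8 lay above 1%. Those 8 libraries came from 6 patients, 5 of them in the netazepide arm. There was 1 among the 9 placebo libraries before, 1 among the 9 after, 3 among the 10 netazepide libraries before and 3 among the 10 after. Gastric surface and neck mucous genes (MUC5AC, TFF1, TFF2, GKN1 and others) took 4.96% ± 2.83 of counts and intestinal goblet and enterocyte genes (MUC2, TFF3, CDX2 and others) 2.88% ± 1.76 (SD, n = 38). Parietal and chief cell genes of gastric oxyntic glands took 0.569% ± 1.16. The first principal component of log2 CPM held 34.8% of the variance and followed the squamous score (absolute r = 0.935 across libraries, a description with no test). The next component held 18.3% and followed the gastric mucous score (absolute r = 0.809) and the intestinal score (absolute r = 0.724).

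**Figure D1:**
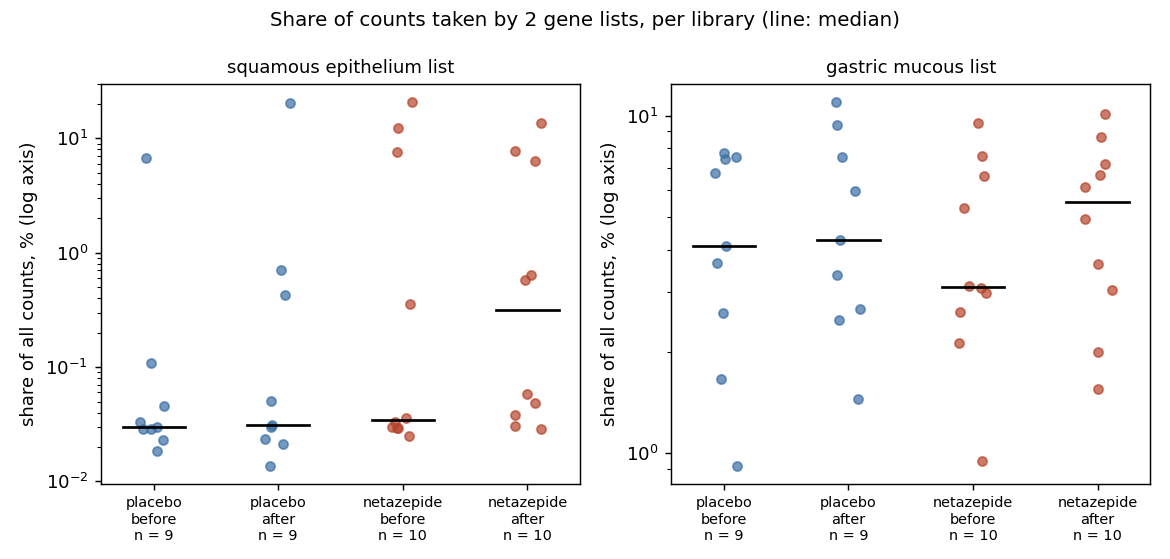
Share of all counts, in percent on a log axis, taken by the squamous epithelium list (left) and by the gastric mucous list (right) in each library of the 4 groups; each point is 1 library and the line is the group median. Most libraries lie near the median squamous share of 0.0371%, and 8 lie above 1%. The group median after netazepide, 0.316%, lies above those of the other groups (0.0302% to 0.0345%).

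After 12 weeks of netazepide, the gene of smallest p was PKNOX2, a homeobox transcription factor, at 4.80 ± 1.88 CPM before and 2.54 ± 1.25 CPM after (SD, n = 10). Its log2 fold change was -0.97 (SE 0.19), with a higher level after treatment in 0 of 10 patients. ACTC1, the cardiac alpha-actin, was also among the 10 genes of smallest p on the lower side, with a log2 fold change of -2.44 (SE 0.57), from 7.82 ± 9.90 to 2.38 ± 5.04 CPM. Neither passed the threshold. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.78 for PKNOX2 and 0.97 for ACTC1. It called 0 of 15953 genes in the netazepide arm. At an unadjusted p under 0.05 lay 751 (344 higher, 407 lower), 4.71% of those tested. With no changed gene such a threshold takes a share of 0.05 on average, so this count is no excess. DESeq2 called 2 genes, the same PKNOX2 (log2 fold change -0.96, adjusted p = 0.0165) and ACTC1 (-2.67, adjusted p = 0.00728). Limma-voom called 0, with 801 at an unadjusted p under 0.05.

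The other genes of smallest p on the lower side did not pass either. They were ZNF837 (log2 fold change -0.76), SLC25A29, a mitochondrial carrier of basic amino acids (-0.43), SRCIN1, an inhibitor of SRC signalling (-0.77), LOC100507403 (-1.10), CCDC92 (-0.28), CEACAM19 (-0.50), BCORL1, a transcriptional corepressor (-0.47), and OXER1, a receptor for oxidised eicosanoids (-0.98). On the higher side stood BMS1P1 (1.31), C1orf55 (0.37), the ubiquitin ligase TRIM2 (0.31), the Golgi mannosidase MAN1A2 (0.36), CHM, a Rab escort protein (0.44), the mRNA decapping enzyme DCP2 (0.31), ZNF761 (0.32), the BRCA1 partner BARD1 (0.63), NUFIP2 (0.20) and NUS1 (0.37). The adjusted p of each of these was 0.97. BMS1P1 is a pseudogene of BMS1 and its reads may be split between copies, and the zinc finger genes ZNF837 and ZNF761 belong to a large family with similar sequence.

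None of the 17 gene lists fixed before the data were examined passed for its score change after netazepide. In the exact sign-flip test over the 10 patients 0 passed (2-sided, smallest exact p = 0.143, adjusted 0.81), and 0 lay under an unadjusted exact p of 0.05. With 10 patients a list alone could pass after adjustment only if all 10 moved the same way. In no list did a member pass FDR 0.05, over all genes or adjusted over the list alone (0 in both). The proliferation list, 30 cell cycle genes, had a mean score change of 0.12 (SE 0.23, n = 10; -0.0525 to 0.25 with each patient left out in turn), with TOP2A at a log2 fold change of 0.39 and CDK1 at 0.27. The list of gastrin signalling and gastrin-responsive genes had the smallest exact p, with a mean change of 0.34 (SE 0.21; 0.22 to 0.47 in the same way), higher in 6 of 10 patients. Its members of smallest p were SLC18A2, the vesicular monoamine transporter (log2 fold change 0.26), REG1A, a secreted lectin of regenerating gastric mucosa (2.06), TPH1, the serotonin-synthesising hydroxylase (0.95), and the collagenase MMP1 (1.10), each with adjusted p = 0.97.

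In lists of the epithelial types of the lesion the spread between patients exceeded the mean change. The gastric mucous list had a mean change of 0.44 (SE 0.40; 0.21 to 0.65 with each patient left out in turn) after netazepide with all 16 members on the higher side, among them SULT1C2 (log2 fold change 0.45) and AQP5 (0.65). For the intestinal list the mean change was -0.37 (SE 0.74; -0.79 to 0.12 with each patient left out in turn; higher in 5 of 10 patients), with 23 of 26 members on the lower side, among them GUCA2B (-0.77) and ANPEP (-0.63). The oxyntic list stood at 0.05 (SE 0.91; CKB at -0.45, GIF, the intrinsic factor gene, at -1.54), with -0.69 to 0.53 when each patient was left out in turn. The squamous list stood at 0.60 (SE 1.72; -0.36 to 1.70 in the same way; SPRR3 at 1.57, SPRR2A at 1.38). Without the replicate block GIF turned to 1.69, SPRR3 to -0.19 and SPRR2A to -0.33. Enteroendocrine genes had a mean change of -0.23 (SE 0.27), with FEV at -1.23 and RFX6 at -0.70 on the lower side and TPH1 at 0.95 on the higher. The enteroendocrine score was lower in 8 of 10 patients, and the mean lay from -0.46 to -0.12 with each patient left out in turn. Without the patient whose change stood apart its exact sign-flip p was 0.0117 (unadjusted, n = 9), 1 of 3 under 0.05 among the 170 tests of the 17 lists with 1 patient left out, beside the gastrin-responsive (exact p = 0.0312) and smooth muscle (exact p = 0.0391) lists. In 9 of the 17 lists, those of proliferation, intestinal, oxyntic and squamous genes, adenocarcinoma drivers, T and natural killer cells, B and plasma cells, macrophages and fibroblasts, the sign of the mean turned when 1 patient was left out. The stem cell, Wnt and Notch list stood at -0.07 (SE 0.08; -0.11 to -0.0214 with each patient left out; LRIG1 0.32, DLL1 -0.34) and the oesophageal adenocarcinoma drivers at 0.02 (SE 0.05; ERBB2 -0.30, MDM2 0.20).

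Among immune and stromal lists in the netazepide arm, inflammation had a mean change of 0.15 (SE 0.32; 0.0079 to 0.33 with each patient left out in turn; IL33 0.46, LCN2 0.51), and T and natural killer cells 1 of -0.12 (SE 0.25; GZMB -0.46, CD3G 0.43). The change was 0.18 for B and plasma cells (SE 0.31; CR2 1.21, CD79B 0.42) and 0.13 for macrophages, neutrophils and mast cells (SE 0.23; MS4A2 0.31, KIT 0.34). Fibroblasts and endothelium stood at 0.03 (SE 0.19; CLDN5 -0.48, FAP 0.41) and immediate early and heat shock genes at -0.14 (SE 0.15; -0.25 to -0.0861 with each patient left out; NR4A1 -0.52, JUND -0.17). Xenobiotic metabolism stood at -0.10 (SE 0.14; -0.18 to -0.0295 in the same way; AKR1C1 -0.36, CYP2B6 -0.94). Smooth muscle genes had a mean change of -0.38 (SE 0.33; -0.63 to -0.26 with each patient left out in turn, and -0.12 without the 2 largest falls), with all 12 members on the lower side, DES at -0.84 and ACTG2 at -0.60, and 2 of 10 patients higher after treatment. When each list was set against the other genes (camera), 3 lists passed with a preset correlation and 0 of 17 with an estimated correlation, where each of the 3 had adjusted p = 0.907. Without the patient with disagreeing labels 1 list passed with the preset correlation, and without the squamous-rich patients 7. The 3 were gastrin-responsive genes (higher, adjusted p = 0.0277), gastric mucous genes (higher, adjusted p = 0.00329) and smooth muscle genes (lower, adjusted p = 0.00329).

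**Figure D2:**
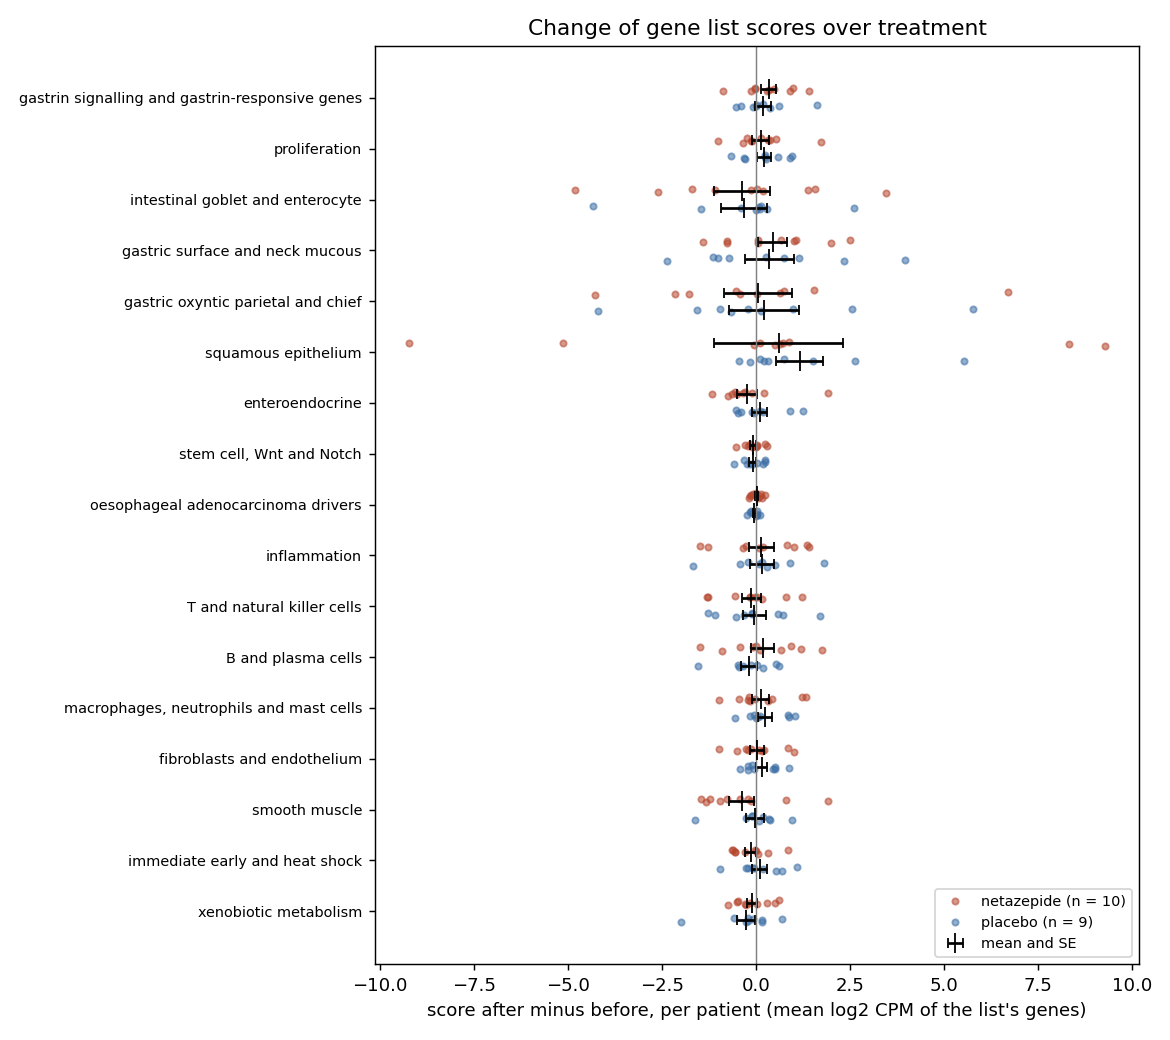
Change of each gene list score (after minus before, mean log2 CPM of the list's genes) in each patient of the netazepide arm (red, n = 10) and the placebo arm (blue, n = 9); the black bar gives the mean and its SE. The mean change of the proliferation list was 0.12 on netazepide and 0.21 on placebo, and among the changes on netazepide the squamous list has the widest spread between patients.

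CCKBR, the receptor that netazepide blocks, was at or below the limit of detection in most libraries and above it in 13 of 38, with a highest value of 15.6 CPM. Its reads numbered 496 over all libraries, 18 had none, and the gene fell below the filter on low counts and was not tested with the other genes. CCKBR stood at 0.714 ± 1.64 CPM before and 1.28 ± 3.46 CPM after netazepide (SD, n = 10; exact sign-flip p = 0.781), and at 1.15 ± 2.37 and 2.32 ± 5.05 CPM on placebo (SD, n = 9; exact sign-flip p = 0.672). A library with no read allows up to 0.212 to 0.403 CPM, depending on its total (3 counts, counting error only). GAST, the gastrin gene, had 79 reads in 13 libraries and was not tested with the other genes. It stood at 0.159 ± 0.444 CPM before and 0.325 ± 0.622 CPM after netazepide (exact sign-flip p = 0.594). On placebo it stood at 0.207 ± 0.359 and 0.0791 ± 0.205 CPM (exact sign-flip p = 0.188). The exact permutation p for the difference between arms was 0.365.

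The marker genes named in advance did not pass in the netazepide arm. MKI67, the Ki-67 proliferation antigen, stood at 172 ± 63.8 CPM before and 194 ± 60.6 CPM after (SD, n = 10), a log2 fold change of 0.22 with a 95% interval from -0.34 to 0.77. With each patient left out in turn, the mean change of MKI67 in log2 CPM (0.24 with all) lay from -0.00237 to 0.39, and the sign turned for 9 of the 10 tested marker genes, all but CHGA. For CHGA, the chromogranin of endocrine cells, the log2 fold change was -0.43 (interval -1.43 to 0.56), and the mean change in log2 CPM went from -0.52 to -0.16 without 1 patient. For HDC, the histamine-synthesising enzyme of enterochromaffin-like cells, it was -0.06 (-0.97 to 0.84). The stem cell markers LGR5 (-0.03; -0.92 to 0.86) and DCLK1 (-0.11; -0.62 to 0.41) had intervals on both sides of 0. So had the intestinal genes CDX2 (-0.17; -1.42 to 1.08), MUC2 (-0.58; -3.21 to 2.04) and TFF3 (-0.28; -1.83 to 1.27), the squamous keratin KRT5 (0.09; -2.86 to 3.04) and the proton pump subunit ATP4A (-0.58; -6.65 to 5.48). For 13936 genes, 87.4% of those tested, the 95% interval of the netazepide change lay within a 2-fold change in either direction. Without the replicate block the log2 fold changes of LGR5, MUC2, TFF3, KRT5 and ATP4A turned to 0.0169, 0.42, 0.0863, -1.04 and 2.25, and without the 3 patients whose labels disagree on number or time CDX2, MUC2 and TFF3 turned to 0.56, 0.80 and 0.78.

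**Figure D3:**
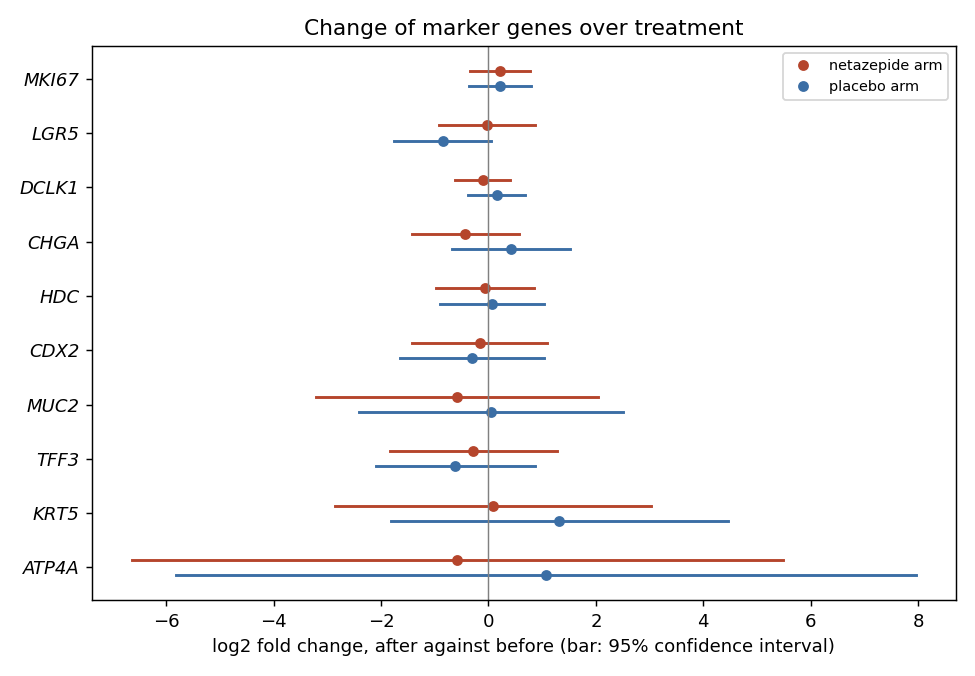
Log2 fold change after against before treatment of 10 marker genes in the netazepide arm (red) and the placebo arm (blue), each with its 95% confidence interval (bar) from edgeR. Every interval includes 0, and the intervals of KRT5 and ATP4A are the widest.

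The placebo arm shows the change over the same interval and repeat biopsy without the drug. Its genes of smallest p were EGFL6, a secreted EGF-like protein, at 0.428 ± 0.935 CPM before and 1.77 ± 2.47 CPM after (SD, n = 9; log2 fold change 2.51, SE 0.61), and, on the lower side, SUV420H2, a histone methyltransferase (-0.53, SE 0.14). EFNA1, an ephrin ligand, stood at 48.2 ± 16.0 and 31.8 ± 6.43 CPM (-0.56, SE 0.15). None passed. EdgeR called 0 of 15953 genes in the placebo arm (smallest adjusted p = 0.997), with 454 (271 higher, 183 lower) at an unadjusted p under 0.05, 2.85% of those tested. DESeq2 called 0 and limma-voom 0. Others on the higher side were the ribosome biogenesis genes NOL11 (0.26) and GTPBP4 (0.36), the proteasomal deubiquitinase USP14 (0.33), ZNF131 (0.25), the unfolded protein response sensor ATF6 (0.23), SNORD31 (0.60), AIMP1 (0.28) and ZNF167 (0.76). On the lower side stood LRRC57 (-0.29), HINFP (-0.29), MED9 (-0.31), the linker histone gene HIST1H1C (-0.64), the epithelial transcription factor ELF3 (-0.39), TMUB2 (-0.26), C19orf77 (-0.51) and IGBP1 (-0.24). SNORD31 is a small nucleolar RNA that lies within another gene, so its reads are uncertain.

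On placebo 0 of the 17 list scores passed the exact sign-flip test (smallest exact p = 0.0625, adjusted 0.81, for the squamous list). With 9 patients a list alone could not pass after adjustment over the 17 lists, even if every patient moved the same way. The test therefore says little about whether a list changed on placebo. Of the list members, 0 passed FDR 0.05 over all genes or adjusted over the list alone. The squamous list had a mean change of 1.16 (SE 0.63, n = 9; 0.61 to 1.36 with each patient left out in turn, with a smallest exact p of 0.0234, unadjusted, among 153 such tests of the 17 lists), with all 30 members on the higher side, among them MAL (log2 fold change 2.30) and KRT4 (2.09). All 30 proliferation genes lay on the higher side too, with a mean score change of 0.21 (SE 0.19; 0.12 to 0.32 in the same way), MCM6 at 0.35, MCM4 at 0.30 and MKI67 at 0.22 (95% interval -0.36 to 0.80). CHGA stood at 0.42 (-0.68 to 1.52), its mean change in log2 CPM going from 0.59 to 0.0378 without 1 patient, and LGR5 at -0.85 (-1.76 to 0.06). Set against other genes, 7 lists passed with the preset correlation and 0 with an estimated correlation, where each of the 7 had adjusted p = 0.813. On the higher side were proliferation, squamous epithelium, oxyntic glands (BHLHA15 0.43, ESRRG 0.48), macrophages, neutrophils and mast cells (CXCR2 2.48, CD163 0.50) and fibroblasts and endothelium (COL1A1 0.29, KDR 0.24). On the lower side were intestinal genes (FCGBP -0.47, LGALS4 -0.36) and xenobiotic metabolism (CYP3A5 -0.36, CYP1B1 -0.62). With each patient left out in turn, the mean lay from -0.38 to -0.0457 for the xenobiotic list (-0.26 with all), from 0.14 to 0.34 for the macrophage list and from 0.0582 to 0.22 for the fibroblast list, and it took both signs for the intestinal (-0.33; -0.70 to 0.17) and oxyntic (0.21; -0.49 to 0.76) lists. The squamous shares of counts in these libraries had medians of 0.0302% before and 0.0313% after, while the means, 0.788% ± 2.25 and 2.39% ± 6.68, rested on the 1 library above 1% at each time.

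The comparison of the change on netazepide with that on placebo is the randomised one. LRRC57 had the smallest p among genes with a higher change on netazepide (difference of log2 fold changes 0.42, SE 0.12; higher after treatment in 7 of 10 netazepide and 0 of 9 placebo patients). LOC100507218 had the smallest among those with a lower change (-1.81, SE 0.46; 0 of 10 and 8 of 9). PKNOX2 (-1.01, SE 0.27) and EGFL6 (-2.85, SE 0.80) were on the lower side as well. None passed. EdgeR called 0 of 15953 genes for the difference between arms (smallest adjusted p = 1.00), with 166 (55 higher, 111 lower) at an unadjusted p under 0.05, 1.04% of those tested. DESeq2 called 0 and limma-voom 0. The remaining genes of smallest p were LOC100506161 (1.20), BMS1P1 (1.71), ZNF761 (0.43), LOC400657 (0.41), the apoptosis inhibitor BIRC2 (0.33), TRIM2 (0.35), the cyclic GMP-dependent kinase PRKG2 (0.88), LOC340544 (0.68) and LOC149837 (1.05) on the higher side. On the lower side they were ZNF837 (-0.92), ZXDC (-0.26), ZSWIM7 (-0.38), TOB2P1 (-1.22), LOC400604 (-1.25), MPP2 (-0.87) and FOXS1 (-1.08).

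The change in MKI67 differed between the arms by -0.01 on the log2 scale, with a 95% interval from -0.81 to 0.80. Its difference in mean log2 CPM change was 0.0245, and -0.22 to 0.17 with each patient left out in turn, when 7 of the 10 tested marker genes turned sign. The proliferation list had a difference of -0.09 (SE 0.29; -0.26 to 0.0383 with each patient left out in turn; exact permutation of the arm labels, p = 0.774, adjusted 0.98), with CCNE2 at -0.30 and E2F1 at -0.42. The gastrin-responsive list differed by 0.14 (SE 0.30; 0.0192 to 0.32 with each patient left out; SLC18A2 0.27, REG1A 2.02). Its sign turned with the median over members (-0.26) and with the patient with disagreeing labels as placebo (-0.0120). The other marker genes named in advance lay between ATP4A (-1.66) and LGR5 (0.82), with CHGA at -0.85 (interval -2.33 to 0.63). The difference in the mean log2 CPM change of CHGA was -1.11, and -0.55 without 1 patient. The signs for MKI67 and ATP4A turned with DESeq2, to 0.00368 and 0.20, and ATP4A stood at 1.51 with the squamous score as a covariate. Without the 3 patients whose labels disagree on number or time MKI67 stood at 0.33 and the proliferation list at 0.15. Of the 17 list scores 0 differed between the arms (smallest exact p = 0.292, adjusted 0.98), and 0 list members passed FDR 0.05 over all genes or adjusted over the list alone. Against other genes, 4 lists passed with the preset correlation at adjusted p = 0.0193 each and 0 with an estimated correlation, where each of the 4 had adjusted p = 0.929. With the patient with disagreeing labels as placebo 0 passed with the preset correlation, and without the squamous-rich patients 7. B and plasma cells (CR2 2.12, CD79B 0.74) and xenobiotic metabolism (CYP1B1 1.20, AKR1C1 -0.38) had a higher change on netazepide, and the squamous (TP63 -1.62, MAL -1.81) and smooth muscle (ACTG2 -0.63, HSPB6 -0.58) lists a lower one. The sign for TP63 turned to 0.21 with limma-voom. It also turned with the squamous score, of which TP63 is a member, as a covariate (0.0685) and with 3 scores (0.72). The mean difference took both signs with each patient left out in turn for the squamous (-1.52 to 0.53) and xenobiotic (-0.0542 to 0.28) lists. It lay from 0.18 to 0.54 for B and plasma cells (0.35 with all, -0.10 without the squamous-rich patients) and from -0.61 to -0.24 for smooth muscle (-0.36 with all). The 95% interval lay within a 2-fold difference for 12046 genes (75.5%). In simulated counts 44.8% of genes with a 2-fold difference in change were recovered, against 71.6% for a 2-fold change within the netazepide arm. Simulated genes varied independently of one another, unlike the real ones. For the difference, 4.83% of the unchanged simulated genes lay under an unadjusted p of 0.05, against 1.04% of the real genes. The recovery rates therefore need not hold for the real libraries.

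Before treatment RNASE7, an antimicrobial ribonuclease of stratified epithelia, stood at 24.5 ± 40.1 CPM in the netazepide arm (SD, n = 10) and 0.356 ± 0.397 CPM in the placebo arm (n = 9), a log2 difference of 6.05 (SE 1.53). The keratinocyte gene KPRP (7.12) and LYPD2 (5.50) lay on the same side, beside NPL (0.63) and PSORS1C2 (1.22). On the lower side CYP1A1, a cytochrome P450 of xenobiotic metabolism, was at 0.629 ± 0.886 CPM in the netazepide arm against 208 ± 429 in the placebo arm (-8.40, SE 1.86), while the medians were 0.391 and 0.530 CPM. CYP1B1 was at 2.58 ± 1.69 against 21.2 ± 34.1 CPM (-3.04, SE 0.75; medians 2.12 and 4.48), with KIAA0319 (-1.78), ZNF594 (-0.61) and LOC149837 (-1.52). None passed with edgeR, which called 0 of 15953 genes (512 at an unadjusted p under 0.05, 3.21% of those tested). DESeq2 called 9: SPRR1A, SPRR2E, HEPHL1, KRT6C, KRT6A, RNASE7 and TGM1 higher in the netazepide arm, CYP1B1 and KIAA0319 lower. Of these, SPRR1A, SPRR2E, HEPHL1, KRT6C, KRT6A and TGM1 were named after their values were seen. For those genes the methods differed in the estimate itself. SPRR1A, KRT6C and HEPHL1 stood at 6.53, 5.88 and 3.89 with DESeq2 and at 2.53, 1.15 and 0.78 with edgeR. TGM1 stood at 5.85 and 1.86. In the netazepide and placebo arms SPRR1A was at 1218 ± 2318 and 209 ± 620 CPM, and TGM1 at 235 ± 433 and 64.5 ± 188 CPM. These means lie close to edgeR's estimates and far from those of DESeq2. The DESeq2 calls of these 2 genes therefore do not show a difference between the arms. EdgeR's unadjusted p lay from 0.231 (SPRR1A) to 0.573 (KRT6C) for them. The estimates for RNASE7, CYP1B1 and KIAA0319 were close with both methods. The squamous share before treatment was 4.14% ± 7.27 in the netazepide arm and 0.788% ± 2.25 in the placebo arm, with medians of 0.0345% and 0.0302%. Without the patients with over 1% squamous counts the log2 difference of RNASE7 was -0.23. KRT6A and KRT6C are near-identical paralogs, so reads could be split between them.

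After treatment CNTFR, a subunit of the ciliary neurotrophic factor receptor, was at 1.97 ± 0.810 CPM in the netazepide arm (SD, n = 10) and 10.5 ± 10.6 CPM in the placebo arm (n = 9), a log2 difference of -2.41 (SE 0.51). LOC151009 (-0.69), SNORD31 (-0.58), VPS37D (-1.26) and the replication helicase gene MCM5 (-0.36) were the next on the lower side. On the higher side stood the neutrophil surface gene CD177 (3.58), GPR110 (1.04), the autophagy receptor OPTN (0.31) and PSORS1C2 (0.96). EdgeR called 0 of 15953 genes after treatment, with 230 (82 higher, 148 lower) at an unadjusted p under 0.05, 1.44% of those tested. DESeq2 called 1, CNTFR (log2 difference -2.40, adjusted p = 0.0112).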

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

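The tests of squamous tissue as what hid a change, of low read numbers, of a change in smooth muscle genes in a few biopsies and of their lowering by netazepide, of squamous tissue as the origin of squamous transcripts and of netazepide as their origin were chosen after the result was seen.

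No gene passed FDR 0.05 for the change on netazepide, the change on placebo or the difference between them with edgeR, while DESeq2 called 2, 0 and 0 genes. At an unadjusted p under 0.05 lay 751, 454 and 166 genes with edgeR, 4.71%, 2.85% and 1.04% of those tested. None of these exceeds the share of 0.05 that such a threshold takes on average with no changed gene. Leaving out the patient with disagreeing labels brought no gene past the threshold: 0 genes passed in the netazepide arm or in the difference with edgeR (834 and 182 at an unadjusted p under 0.05). A fit with fewer patients has less power, so it cannot exclude that this patient hid a change. Low read numbers are argued against for the 10400 genes with a mean above 10 CPM, whose median SE of the netazepide change was 0.116 on the log2 scale, but not for the 5553 others, at 0.251. A change hidden by squamous tissue stays open: with the squamous score as a covariate beside the replicate block 0 genes passed in the netazepide arm (1107 at an unadjusted p under 0.05), but the smallest adjusted p was 0.0727, against 1 for the difference between arms (198) and 0.999 on netazepide without the squamous-rich patients (562). The last of these fits held only 5 netazepide and 8 placebo patients and had less power. Over the alternatives other than DESeq2 the smallest adjusted p ranged from 0.0727 to 1 on netazepide.

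Splits of the patients say nothing about chance for these counts, since any split gives at least the real 0: 24 of 24 did in the netazepide arm (the real one and 23 random ones; highest other 5), 24 of 24 in the placebo arm (highest other 0), 24 of 24 for the difference (highest other 582), 40 of 40 before treatment (the real one and 39 random ones; highest other 205) and 40 of 40 after treatment (highest other 0). For the genes at an unadjusted p under 0.05 chance cannot be excluded: the real and the highest other counts were 751 and 2865 on netazepide, 454 and 852 on placebo, 166 and 3451 for the difference, 512 and 2603 before treatment and 230 and 2821 after. The 582 genes came from 1 random split and calls before treatment from 2, while the other splits of these 2 comparisons called 0; such splits point to a structure of the samples, whose cause was not tested.

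Smooth muscle genes were lower after netazepide by the set test with a preset correlation, with a mean score change of -0.38 and 8 of 10 patients lower, but that call was lost with an estimated correlation (adjusted p = 0.907 with an estimated correlation). That netazepide lowered them was not shown and stays open, since the exact sign-flip p over the 10 patients was 0.279. A change in a few patients' biopsies also stays open, since the median change was -0.59 but patients lay on both sides of 0, and the mean was -0.12 without the 2 largest falls and -0.63 to -0.26 with each patient left out in turn. Biopsies that reach the muscle layer beneath the mucosa to different depths could give such values, and the depth of a biopsy was not tested.

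Squamous transcripts varied from 0.0138% to 20.9% of a library's counts. Netazepide as their origin is argued against by libraries taken before treatment, of which 1 reached 20.9%, and the exact permutation p for the difference between arms in the change of the score was 0.785. A rise on netazepide beside that was not shown and stays open. The median share was 0.0345% before and 0.316% after netazepide, while the mean went from 4.14% to 2.93%. The total count of a library as the source of the whole range from 0.0138% to 20.9% is argued against by the totals, which ranged only from 7444670 to 14172500. After treatment, libraries with squamous shares of 20.2% (placebo) and 13.8% (netazepide) had totals of 9676690 and 8238780, under the mean of 10112000. A relation of the share with the total before treatment stays open. There rho was 0.353 (permutation p = 0.14, adjusted 0.28 over 2 relations, n = 19) and Pearson's r 0.781 (permutation p = 0.002, adjusted 0.004). But r was 0.064 without the 2 libraries farthest from the median total, so that the relation rests on those libraries. After treatment rho was 0.0035 (permutation p = 0.991, adjusted 0.991) and r -0.184 (permutation p = 0.435, adjusted 0.435), so that no relation was shown at that time. Before treatment r was 0.854 within the netazepide arm, which goes with a relation, and 0.00699 within the placebo arm, which goes against it. Squamous tissue in the biopsy is a candidate source: the 30 squamous genes moved together over the libraries with a median pairwise r of 0.957, and 435 of 435 pairs lay above 0.5, the lowest at 0.637.

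In 21 of 166 groups of values tested, 1 value stood far from the others (its gap to the next value as a share of the group's range is given below), where chance gives about 1 in 20 groups. The groups are not independent, since marker genes belong to lists and changes reuse the levels. A single library can therefore give several of these values, and the 21 cannot be set against that rate as separate findings. Before placebo the highest value stood apart for the oxyntic (0.585), squamous (0.571), inflammation (0.542) and fibroblast and endothelium (0.505) scores and for ATP4A (0.698). After placebo the lowest value of CDX2 stood apart (0.602). Before netazepide the lowest value stood apart for the intestinal (0.587) and xenobiotic (0.574) scores and for MKI67 (0.535), CDX2 (0.5501), MUC2 (0.656) and TFF3 (0.674). After netazepide the highest value of HDC (0.469) and the lowest of CDX2 (0.647) stood apart. Among changes on netazepide, the highest of the oxyntic (0.468) and enteroendocrine (0.5495) scores and the lowest of CHGA (0.592) stood apart. Among changes on placebo, the lowest of the smooth muscle (0.522) and xenobiotic (0.530) scores and the highest of CHGA (0.524) and KRT5 (0.547) did.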

How the results depend on the processing

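Chosen after the data were seen were leaving out the 6 patients with a library of over 1% squamous counts, the 3 scores as covariates, leaving out the 3 patients whose labels disagree on number or time, leaving out each patient in turn, and the choices about patients in the camera tests. The first of these took out 5 netazepide patients and 1 placebo patient and left 5 and 8, so its values rest on few netazepide patients. When 1 patient was left out, the sign of the mean change turned in 9 of 17 lists on netazepide, 8 on placebo and 10 for the difference, and in 9, 4 and 7 of the 10 tested marker genes.

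Of 59 counts of genes under the alternatives, 56 were 0 as in the fits reported. DESeq2 called 2 genes in the netazepide arm, 9 between the arms before treatment and 1 after; the cause was not tested. With no replicate block edgeR called 0 genes in each arm and for the difference, with 302, 222 and 78 at an unadjusted p under 0.05. Over the alternatives the genes at an unadjusted p under 0.05 ranged from 302 to 1422 on netazepide, 222 to 879 on placebo, 78 to 429 for the difference, 363 to 942 between arms before treatment and 197 to 1077 after. Less could be seen for genes of low level, as the median SE of the netazepide change was 0.116 above a mean of 10 CPM and 0.251 below. These SEs include the variation between patients, and the share of counting error in them was not tested.

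Of 39 counts of lists past a test, 27 were within 1.5 times the value reported and 12 moved further. The 27 include the counts of score changes, which were 0 in every setting. All 12 that moved were counts of lists set against other genes or tested with fry, and on netazepide every such count moved. From 3 lists on netazepide, 7 on placebo and 4 for the difference, an estimated correlation gave 0, 0 and 0 and fry 0, 0 and 0. For netazepide, leaving out the patient with disagreeing labels gave 1 list, counting the patient as placebo 1, leaving out the squamous-rich patients 7 and leaving out the 3 patients with a disagreeing number or time 5. For the difference, counting the patient as placebo gave 0 and leaving out the squamous-rich patients 7.

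None of the list scores passed its adjusted exact test under the alternatives run. For the sign-flip tests this says little. With 9 or fewer patients in an arm, a list alone cannot pass after adjustment over 17 lists. Without the squamous-rich patients 5 netazepide patients were left, with whom no list could pass. Without the 3 patients with a disagreeing number or time 7 were left. Of 357 alternative values, 320 kept their sign. With the median over members, the change turned to 0.0876 for the stem cell list on netazepide, to 0.00013 (stem cell), 0.0470 (adenocarcinoma drivers) and 0.0507 (smooth muscle) on placebo, and for the difference to -0.26 (gastrin-responsive), -0.0195 (drivers), 0.0849 (inflammation), 0.0217 (T and natural killer cells) and 0.0635 (macrophages). Without the patient with disagreeing labels it turned to -0.0188 (oxyntic) and -0.000161 (drivers) on netazepide and to 0.0520 (intestinal) and -0.0734 (gastric mucous) for the difference. With the patient as placebo it turned to -0.0257 (oxyntic) and -0.00757 (drivers) on netazepide and to -0.0120 (gastrin-responsive), 0.12 (intestinal), -0.25 (gastric mucous) and -0.00579 (stem cell) for the difference. Without the squamous-rich patients it turned to 0.00163 (intestinal), -0.31 (oxyntic), -0.0125 (inflammation), -0.26 (B and plasma cells), -0.20 (macrophages) and -0.0665 (fibroblasts) on netazepide, and to -0.0245 (gastrin-responsive), 0.40 (intestinal), -0.0610 (gastric mucous) and -0.10 (B and plasma cells) for the difference. Without the 3 patients with a disagreeing number or time it turned to 0.52 (intestinal), -0.85 (oxyntic), 0.00845 (stem cell), -0.00817 (B and plasma cells) and -0.0862 (fibroblasts) on netazepide, and to 0.15 (proliferation), 0.86 (intestinal) and -0.23 (gastric mucous) for the difference. The causes were not tested.

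Of 2072 alternative log2 fold changes of named genes 2030 kept their sign and their side of the threshold, 6 passed under DESeq2 alone, and 36 turned in sign. Many of these genes were named for a small p in the same data, and none had passed in the fits reported. The number kept was therefore partly fixed in advance and says little about how firm the values are. On netazepide, no replicate block gave LGR5 0.0169, MUC2 0.42, TFF3 0.0863, KRT5 -1.04, ATP4A 2.25, GIF 1.69, SPRR3 -0.19 and SPRR2A -0.33. LGR5 was 0.0121 without the patient with disagreeing labels and 0.00314 with the patient as placebo. With 3 scores as covariates CDX2 was 0.0606, MUC2 0.30, TFF3 0.0315 and KRT5 -0.135, and with the squamous score KRT5 was -0.12 and ATP4A 0.71. CDX2, MUC2, TFF3 and KRT5 are members of the scores used as covariates. Such a fit takes out much of their own change, so their turns say little about the change on netazepide. Without the squamous-rich patients TFF3 was 0.0855 and MS4A2 -0.00446 on netazepide, MKI67 0.16 for the difference and RNASE7 -0.23 between arms before treatment. Without the 3 patients with a disagreeing number or time CDX2 was 0.56, MUC2 0.80, TFF3 0.78, ANPEP 0.0824 and CD3G -0.28 on netazepide, and MKI67 0.33 for the difference. The difference in MKI67 was 0.0176 with no replicate block, 0.00364 with DESeq2 size factors, 0.00599 at a mean CPM of at least 1, 0.00368 with DESeq2 and 0.0264 with limma-voom. That in ATP4A was 0.20 with DESeq2 and 1.51 with the squamous score, and that in TP63 was 0.21 with limma-voom, 0.0685 with the squamous score and 0.72 with 3 scores. TP63 too is a member of the squamous score, so its last 2 values carry the same limit. The causes were not tested.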

Other observations

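The relations of CYP1A1 with AHRR and of CCKBR with the gene lists were looked at after the levels of CYP1A1 and CCKBR had been seen.

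CCKBR was read mainly in libraries rich in parietal and chief cell genes of oxyntic glands, the gastric glands in which the receptor is known from parietal and enterochromaffin-like cells. Over the 19 libraries before treatment rho between CCKBR and the oxyntic score was 0.818 (permutation p = 5e-05, adjusted 0.0017 over 34 relations) and Pearson's r 0.920 (permutation p = 2e-05, adjusted 0.00034), with r of 0.815 without the 2 libraries farthest from the median score. After treatment rho was 0.775 (permutation p = 3e-04, adjusted 0.0051) and r 0.924 (permutation p = 1e-05, the smallest that the resampling can give, adjusted 0.00034), with r of 0.817 without the 2 farthest. Within the arms r was 0.966 on netazepide and 0.890 on placebo before treatment, and 0.956 and 0.925 after. Other lists passed by rho before treatment but with lower values, among them macrophages, neutrophils and mast cells (rho 0.694, permutation p = 0.0016, adjusted 0.0168; r 0.637, permutation p = 0.0034, adjusted 0.0167), gastric mucous (rho 0.677, permutation p = 0.002, adjusted 0.0168; r 0.690, permutation p = 0.001, adjusted 0.0088), gastrin-responsive (rho 0.644, permutation p = 0.0039, adjusted 0.0257; r 0.706, permutation p = 0.00066, adjusted 0.0075) and fibroblasts and endothelium (rho 0.629, permutation p = 0.0053, adjusted 0.0257; r 0.636, permutation p = 0.0036, adjusted 0.0167). For these lists r was 0.514, 0.678, 0.602 and 0.572 without the 2 farthest libraries. After treatment B and plasma cells passed (rho 0.631, permutation p = 0.0047, adjusted 0.0257). The intestinal score went the other way by r, at -0.724 before (permutation p = 0.0017, adjusted 0.0116) and -0.628 after treatment (permutation p = 0.0053, adjusted 0.0202). By rho it did not pass, at -0.506 (permutation p adjusted 0.081) and -0.536 (adjusted 0.0767). A candidate explanation is that CCKBR reads come with gastric oxyntic glands in the biopsy; a low level of the receptor in the metaplastic epithelium itself was not tested, as 18 of the 38 libraries had no read.

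Differences between patients in the oesophageal adenocarcinoma driver genes and in enteroendocrine genes were partly kept over 12 weeks. The driver score before and after treatment had r = 0.760 over 19 patients (permutation p = 0.00014, adjusted 0.0024 over 17 lists; rho 0.696, permutation p = 0.0012, adjusted 0.0116), r = 0.641 without the 2 patients farthest from the median, and 0.763 and 0.770 within the netazepide and placebo arms. The enteroendocrine score had r = 0.656 (permutation p = 0.0025, adjusted 0.0141; rho 0.686, permutation p = 0.0015, adjusted 0.0116), r = 0.503 without the 2 farthest, and 0.636 and 0.807 within the arms. Of the 17 lists, 5 passed by r, 3 by rho and 2 by both. A cell make-up that is stable over 12 weeks may be behind this, but its test on the intestinal score, named in advance, left it open, with r = 0.379 (permutation p = 0.098, adjusted 0.158; rho 0.253, permutation p = 0.296, adjusted 0.419) and r = 0.020 without the 2 farthest. Within the arms the intestinal r was -0.191 on netazepide and 0.670 on placebo.

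A change shared by both arms, from time or repeat sampling, was not shown and stays open. The mean changes of the arms had r = 0.365 across 15953 genes, which are not independent replicates, and 199 of 1000 random sign flips of whole patients gave a correlation as large in size. The real value lay within the central 95% of the flips, from -0.511 to 0.512, a range too wide to exclude a shared change.

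CYP1A1 and CYP1B1 are targets of the aryl hydrocarbon receptor, as is AHRR, its repressor. Whether such targets move together between libraries stays open. CYP1A1 and AHRR had rho = -0.0965 before treatment (permutation p = 0.693, adjusted 0.978 over 8 relations, n = 19) and -0.0123 after (permutation p = 0.961, adjusted 0.978), with upper 95% bounds of 0.374 and 0.444, and most CYP1A1 levels were near 0. Pearson's r was 0.393 before (permutation p = 0.116, adjusted 0.464; -0.166 without the 2 libraries farthest from the median of CYP1A1) and 0.114 after (permutation p = 0.647, adjusted 0.670; 0.297 without them). Within the arms r before treatment was -0.504 on netazepide and 0.533 on placebo. CYP1A1 and CYP1B1 had r = 0.803 before treatment (permutation p = 0.0018, adjusted 0.0144; rho 0.432, permutation p = 0.0655, adjusted 0.524), which rests on few libraries, since r was 0.105 without the 2 farthest, and r was -0.166 on netazepide and 0.893 on placebo. The median of CYP1A1 before treatment was 0.391 CPM in the netazepide arm and 0.530 CPM in the placebo arm, so that the difference in means rests on few libraries.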
